A study of Mus musculus with 51 samples.

How the data were processed

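Total RNA from sorted mouse epithelial cells was sequenced in 51 libraries of 14 groups (per the labels, NuGEN Ovation Solo libraries on a NovaSeq 6000). Cells were sorted on EpCAM, on a Krt8-YFP reporter or on both, and the gate differs between groups as the report states. The deposited values are read counts per Ensembl gene that the authors made with STAR 2.5.3a and HTSeq. The authors also name edgeR and the builds GRCm38 and mm10, and the annotation release and strand setting are not given in the sources used here. The table held 52636 genes, 10741 of them with no count in any library, and its columns were matched to samples through the raw names in the labels, with 0 columns unused. Of the gene identifiers, 52403 were found in GENCODE release M21 for GRCm38, which gave symbols, gene types and coordinates. For the 97 symbols carried by more than 1 identifier, the identifier with the most counts was taken. Reads of the SmoM2 transgene and of endogenous Smo are counted together, and counts of genes with near-identical copies (Krt6a and Krt6b, the Serpinb3 genes, Sprr2d, Defa24, Rpl29 and Rps2-ps13) and of the pseudogenes Clec2f and BC002163 are uncertain by an unknown amount.

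Library totals ranged from 1.61 M counts upwards, and the floor of a group is 3 counts over its total, from 0.0484 CPM in SmoM2 and 0.0563 in WT to 0.247 in K8YFP+ and 0.466 in gut. Intervals and floors of this kind cover counting error only. Where a group had no count, a fold is given as a lower bound against that floor. CPM are counts scaled by the plain library total, whereas fold changes use TMM scaling, so that a ratio of CPM and a fold change can differ (Sox9 in K8YFP+ and K8YFP- cells is an example). Errors beside CPM are SD between libraries and errors beside log2 folds are SE.

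Genes were tested in R 4.3.3 with edgeR 4.0.16 by its quasi-likelihood F test on counts, with TMM scaling and filterByExpr (minimum count 10, minimum total 15) within the libraries of a fit. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, in two-sided tests. SmoM2 against WT, K8YFP+ against K8YFP-, Sox9cKO against SmoM2 and the junction groups were fitted alone. The 3w and 7w contrasts, the interaction of gate and time, and EpCAM-low against WT came from 1 fit of WT and the 4 time-series groups (22 libraries). Embryo against WT and K8YFP+ against the 3 columnar tissues came from 1 fit of all 51 libraries, because groups of 2 libraries give little spread of their own. This made 15 comparisons, 6 of them main ones. Sox9, Smo, Epcam and Krt8 were also compared by exact permutation tests of log2(CPM + 1), 56 tests adjusted together.

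Gene lists were fixed before the data were examined, as were the comparisons, tests, rule for naming genes and most alternative settings. The 22 lists cover Hedgehog, squamous basal, squamous differentiation, simple epithelial, endoderm factor, gastric, intestinal, secretory, fetal, cell-cycle, Wnt, Notch, BMP and TGF-beta, hair follicle, interferon and stress genes, and markers of fibroblast, immune, endothelial, muscle, neural and enteroendocrine cells. Each list was tested in each comparison by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists, and called members were counted with adjustment over all genes and over the list alone. In the main comparisons the text describes all lists chosen for them beforehand, beside others. Outside them it leaves out some of the lists chosen beforehand and names some that were not. Lists that passed there, with the preset correlation or with both, are therefore not all named.

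Genes named in the text follow a rule, and the text may name fewer than it gives. A result of the SmoM2 and WT comparison that the rule gives is not reported here. It names 15 anchor genes in main comparisons (6 in the others), the 3 called members with the smallest p of each primary list (1 in the others), and the 5 largest folds in each direction (2 in the others). The last are taken among called genes with an absolute log2 fold of at least 1, a mean of at least 5 CPM in the higher group and no overlap between libraries, leaving out unnamed, mitochondrial and sex-linked genes. Genes named outside this rule are marked in the text as chosen after their values were seen.

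The labels do not tie replicate numbers to animals, so pairing was tested through the correlation of residuals between libraries of equal number, over genes passing the filter, with a minimum of 0.1 in every pair. This held for K8YFP+ and K8YFP- (0.29 to 0.41) and for the gates at 3w (0.16 to 0.29). At 7w the lowest was 0.075, and it was 0.13 over genes of at least 10 CPM, so that the choice of genes decides whether 7w counts as paired. Replicate number as a block was therefore tried in every comparison. Other alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, a fit of all 14 groups, a minimum absolute log2 fold of 1, leaving out each library, and leaving out the WT libraries that share a leading number in their raw names. Added after the data were seen were thinning all K8 libraries to the smallest, leaving out libraries by Xist and Y-linked reads, summing WT 3 with 5 and WT 4 with 6, and fitting only the groups compared in the time-series contrasts.

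Overlaps between comparisons were counted among genes tested in both. Where a group is shared, it was divided so that each comparison used 3 libraries of its own, in all 20 ways, and data without any change were simulated from the shared group. The tests were checked on simulated data with 200 changed genes. With edgeR, of 100 genes changed 2-fold and 100 changed 4-fold, 89 and 99 were recovered in SmoM2 against WT, 17 and 80 in K8YFP+ against K8YFP-, 63 and 100 in Sox9cKO against SmoM2, 81 and 99 at the junction, 87 and 99 between the gates at 3w, and 53 and 83 in K8YFP+ against gut. Between 6 and 9 unchanged genes were called. DESeq2 recovered 47 and 87 in K8YFP+ against K8YFP-, with 20 unchanged genes called. Over 78 pairs of libraries within a group, the chi-square per degree of freedom was lowest for WT 3 with 5 (1.92) and WT 4 with 6 (2.47), then 2.71 in a time-series group, and at least 11 in the other WT pairs. Counts alone do not tell whether the low WT pairs are repeat libraries of 1 sample, and all tests with WT treat the 6 libraries as separate unless they are said to be summed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.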

Results

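The series measured total RNA from sorted mouse cells of the oesophagus and neighbouring epithelia in 51 libraries that fall into 14 groups. SmoM2 is an active form of Smoothened, the transducer of the Hedgehog pathway, and was expressed here under a Krt5 driver in basal squamous cells. The oesophageal groups were WT (n = 6, EpCAM-low gate), SmoM2 (n = 6, EpCAM-high gate), SmoM2 cells sorted on a Krt8-YFP reporter into K8YFP+ and K8YFP- cells (n = 3 each, EpCAM-high), and SmoM2 cells with floxed Sox9 (Sox9cKO, n = 4, EpCAM-high). A time series held EpCAM-high and EpCAM-low SmoM2 cells labelled 3w and 7w (n = 4 in each of its 4 groups), without saying from what the weeks were counted. Reference groups were E13.5 embryonic oesophagus (n = 2, gated on EpCAM and YFP), stomach and gut (n = 2 each, gated on YFP), and columnar (n = 4, EpCAM-high with YFP) and squamous cells (n = 3, EpCAM-high without YFP) of the squamocolumnar junction. The gate thus differs together with the group compared for embryo against WT, for the junction and for K8YFP+ against stomach and gut. Library totals ranged from 8.04 to 9.88 M counts (M, mega) in WT, 1.61 to 6.71 M in K8YFP+, 8.53 to 9.34 M in K8YFP- and 7.6 to 9.87 M in Sox9cKO. The 6 SmoM2 libraries held 8.98 M counts or more each and 62.02 M together. Totals lay between 5.06 and 8.4 M in the time series, 4.29 and 7.02 M in the junction groups, and 10.8 and 10.9 M in the embryo. Stomach libraries held 3.19 and 7.63 M counts and gut libraries 2.81 and 3.63 M. Counts of WT 3 and 5, and of WT 4 and 6, differed by a chi-square per degree of freedom of 1.92 and 2.47, against 11 to 35.6 in the other 13 WT pairs, so the 6 WT libraries may stand for 4 samples. Each pair carries 1 sample code in its raw names, but WT 2 shares that of WT 3 and 5 and lies far from both (25 and 26.7), so the code does not mark repeats. Comparisons with WT use 6 libraries and were repeated with these pairs summed. Values below are CPM (counts relative to the library total, mean ± SD) and log2 fold changes from edgeR (± SE) with their adjusted p. Genes are placed on GRCm38. Gli1 (ENSMUSG00000025407) lies on chromosome 10 at 127329882 to 127341974. Ptch1 (ENSMUSG00000021466) lies on chromosome 13 at 63508328 to 63573598. On chromosome 11 lie Sox9 (ENSMUSG00000000567) at 112782224 to 112787760, Krt20 (ENSMUSG00000035775) at 99428403 to 99438150 and Krt13 (ENSMUSG00000044041) at 100117327 to 100121566. On chromosome 15 lie Krt7 (ENSMUSG00000023039) at 101411043 to 101430313 and Krt8 (ENSMUSG00000049382) at 101996698 to 102004482.

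The comparison of SmoM2 with WT cells asked what active Smoothened does to oesophageal epithelial cells. Hedgehog targets rose the most among the genes followed from the start. Gli1, the transcription factor that is both effector and target of the pathway, stood at 220 ± 34.9 CPM in SmoM2 and 0.703 ± 0.277 in WT (n = 6 and 6, log2 fold 8.12 ± 0.19, adjusted p = 1.41e-13). Ptch1, the Hedgehog receptor and a direct target, rose from 19 ± 1.87 to 1390 ± 232 CPM (6.06 ± 0.13), and Gli2 rose by 6.24 ± 0.21. Smo itself rose by 1.35 ± 0.13, with reads of the transgene and of the endogenous gene counted together. Hhip, another target, had 5 counts over the SmoM2 group and 2 over WT and was not tested. Of 14 tested members of the Hedgehog list, 9 rose and 1 (Cdon, a co-receptor, -0.78 ± 0.13, named after its values were seen) fell. Simple epithelial keratins rose from low levels. Krt8 rose to 4.21 ± 2.94 from 0.521 ± 0.32 CPM (2.86 ± 0.53), Krt18 to 3.87 ± 1.6 from 0.845 ± 0.342 (2.05 ± 0.35) and Krt20 to 38.6 ± 11.6 from 0.994 ± 0.53 (5.13 ± 0.35). Krt7 was below the count minimum for testing, at 5.48 ± 3.56 CPM in SmoM2 and 0.633 ± 0.262 in WT. The tight junction genes Cldn8 (2.26 ± 0.20) and Marveld3 (1.32 ± 0.12) rose with them, and Epcam, on which the gates differ, rose by 0.77 ± 0.12. The squamous keratins went different ways. Krt4 and Krt13, made in differentiating oesophageal cells, fell by 2.23 ± 0.29 and 1.17 ± 0.15 on the log2 scale, from 6260 ± 1940 to 1480 ± 638 and from 7760 ± 1640 to 3790 ± 617 CPM. The epidermal keratin Krt10 rose from 21.5 ± 8.37 to 664 ± 159 CPM (4.82 ± 0.24), and the stress-responsive Krt6a and Krt6b, which share much of their sequence, rose by 1.78 ± 0.17 and 2.46 ± 0.28. Basal keratins Krt5 (-0.62 ± 0.17, adjusted p = 0.00586), Krt14 (-0.95 ± 0.16) and Krt15 (-0.78 ± 0.08) fell. The basal regulators Trp63 (0.49 ± 0.10) and Sox2 (1.59 ± 0.22) and the neurotrophin receptor Ngfr (3.01 ± 0.30) rose. Sox9, a factor of embryonic foregut and columnar epithelia, read 107 ± 44.7 CPM in SmoM2 and 89.2 ± 27.2 in WT (0.14 ± 0.26, adjusted p = 0.671; exact permutation test, two-sided, p = 0.413, and p = 0.5 with the WT pairs summed).

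Genes with the largest changes included several near 0 in WT. Abca13, a lipid transporter gene, averaged 62.3 ± 17.5 CPM in the 6 SmoM2 libraries and had no count in WT, at least 1110-fold higher. The secreted Wnt inhibitor Wif1 (49.1 ± 42.2 CPM), the uroplakin gene Upk1b (44.4 ± 25.2) and Wdr72 (13.6 ± 4.15) had no WT count either and were at least 873-fold, 789-fold and 243-fold higher. Slc6a11, a GABA transporter gene, read 171 ± 21.6 against 0.0203 ± 0.0497 CPM. The strongest falls were in Atp12a, a proton-potassium pump gene (-6.35 ± 0.66), Clec2f, annotated as a pseudogene of the C-type lectin family (-6.21 ± 0.52), Cpn1, which encodes carboxypeptidase N (-6.04 ± 0.44), Wnt16 (-4.50 ± 0.49) and the imprinted H19 (-3.86 ± 0.41). Among transcription factors, Sox4 (2.95 ± 0.17) and Sox21 (1.78 ± 0.13) rose, and the imprinted Peg3 fell (-3.60 ± 0.41). Cell-cycle genes Ccnd1 (-1.29 ± 0.14), Cenpf (-1.30 ± 0.17) and Kif11 (-0.91 ± 0.18) fell. By list, 11 of 16 simple epithelial genes rose and 2 fell, 8 of 17 squamous basal genes rose and 5 fell, and 9 of 35 squamous differentiation genes rose and 10 fell. Fetal genes rose in 4 of 11 and fell in 5, and cell-cycle genes rose in 1 of 33 and fell in 9 (6 adjusted over the list alone). Wnt genes rose in 15 of 23 and fell in 5, Notch genes rose in 7 of 11, and BMP and TGF-beta genes rose in 8 of 18 and fell in 3. Hair follicle genes rose in 6 of 11 (1 fell), intestinal genes in 5 of 8 (1 fell), gastric genes in 3 of 5 and endoderm factors in 2 of 5. Secretory genes rose in 1 of 5 (2 fell) and stress genes in 5 of 19 (2 fell), and interferon genes fell in 6 of 10 with 1 higher. Of the markers of other cell types, immune ones rose in 4 of 6 (camera adjusted p = 0.131), fibroblast ones rose in 2 of 8 and fell in 2, endothelial ones moved in 1 of 4 each way and muscle ones in 1 of 3 each way. Neural markers rose in 2 of 3 (0.141), and the 1 tested enteroendocrine marker did not pass. Counts adjusted over the list alone were equal or differed by at most 3 members. Median and mean fold differed in sign for squamous differentiation (-0.19 and 0.135, test downward), secretory (0.269 and -0.569, downward), endothelial (0.188 and -0.16, upward) and muscle genes (0.223 and -0.444, upward), and for fibroblast genes both were below 0 (-0.103 and -0.0802) with the test upward. Camera with a preset correlation was passed by 4 lists, all upward: Hedgehog (adjusted p = 0.000396), Wnt (0.00388), simple epithelial (0.00786) and intestinal (0.0209). With an estimated correlation none did, the adjusted p being 0.145, 0.23, 0.23 and 0.145 in that order. In all, 8034 of 16224 tested genes passed, 4248 higher and 3786 lower in SmoM2, and 7398 with the WT pairs summed, where every named gene and list kept its call. Genotype and EpCAM gate differ together here, so that neither can be given its own share of these differences, and a leading number in the raw library names, 4 to 6 in WT and 1 to 2 in SmoM2, differs with them.

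**Figure D1:**
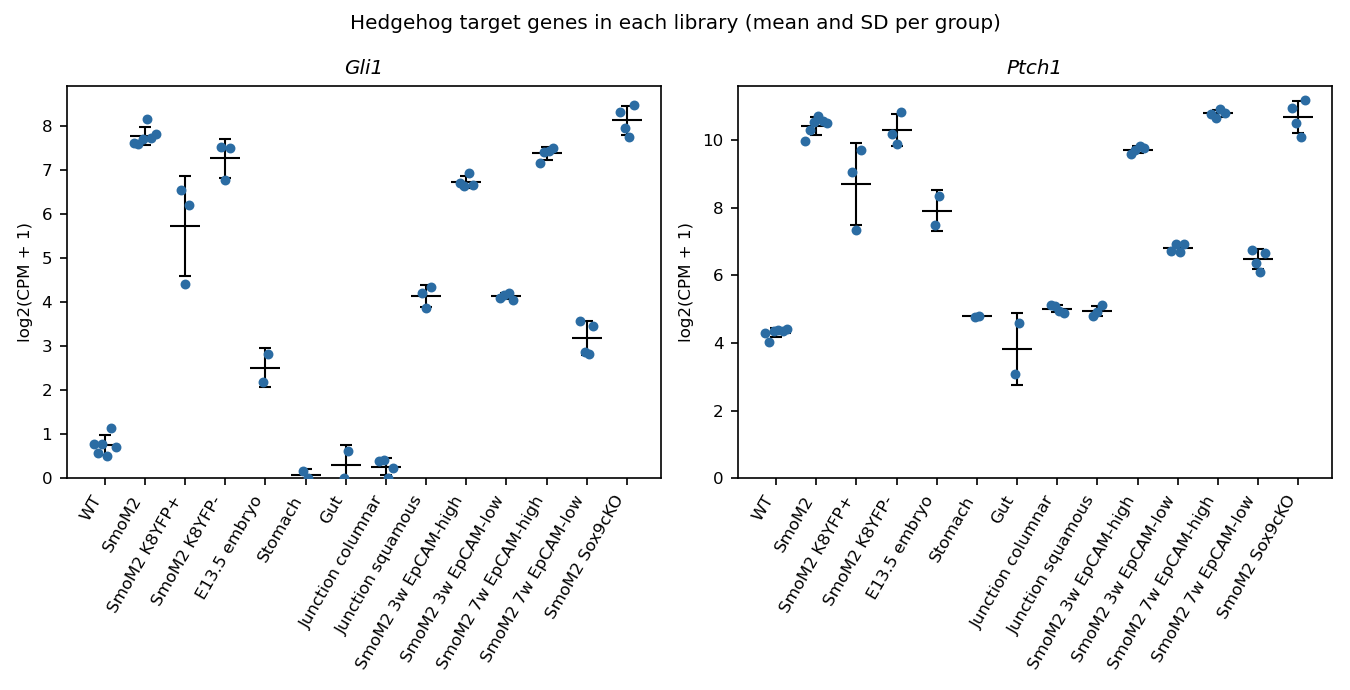
Gli1 and Ptch1 in each of the 51 libraries as log2(CPM + 1), with the mean and SD of each of the 14 groups. WT Gli1 averages 0.703 CPM and SmoM2 Gli1 220 CPM, and in the time series the EpCAM-high groups sit above the EpCAM-low groups for both genes.

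Embryonic oesophagus at E13.5 was set against adult WT as a reference for an immature state (n = 2 and 6). Shh, the ligand of the pathway, read 182 ± 19.5 CPM in the embryo and 0.0381 ± 0.0592 in WT, and Gli1 rose by 2.23 ± 0.38 to 4.87 ± 1.79 CPM. Krt8 rose by 8.53 ± 0.60 to 276 ± 146 CPM and Krt7 by 6.48 ± 0.61 to 83.4 ± 8.45. The fetal growth factor Igf2 rose by 11.27 ± 0.30 to 2370 ± 296 CPM. Sox11 (557 ± 89.2 against 0.0178 ± 0.0436 CPM), Onecut2 (297 ± 414 against 0.0381 ± 0.0592), Prox1 (31.4 ± 4.25 against 0.0207 ± 0.0508) and Prom1 (58.1 ± 15.1 against 0.0588 ± 0.0647) were higher in the embryo, with Onecut2 far apart between its libraries. Krt13 (-8.32 ± 0.43), Krt5 (-4.26 ± 0.42), the squamous differentiation gene Lypd3 (-7.24 ± 0.33) and Ccnd1 (-2.34 ± 0.21) fell. The metallothionein gene Mt4 and the lipoxygenase gene Alox12b had no embryonic count and were at least 1230-fold and 792-fold lower. Sox9 read 165 ± 26.6 CPM (0.35 ± 0.31, adjusted p = 0.323). All 20 tested fetal genes rose (camera adjusted p = 1.4e-11, and adjusted p = 3.01e-06 with an estimated correlation), 33 of 36 squamous differentiation genes fell (1.09e-19, and 0.0311 with an estimated correlation) and 13 of 20 simple epithelial genes rose with 4 lower (0.0121, adjusted p = 0.35 with an estimated correlation). Hedgehog genes rose in 11 of 17 and fell in 2 (0.0265, adjusted p = 0.35 with an estimated correlation). Fibroblast markers rose in 7 of 13 and fell in 1 (0.0423, adjusted p = 0.559 with an estimated correlation, 0.0586 with the WT pairs summed). Col1a1, a fibroblast collagen named after its values were seen, stood at 74.2 ± 44.7 CPM. Muscle markers rose in 7 of 10 and enteroendocrine ones in 5 of 8 without passing as lists (camera adjusted p = 0.105 and 0.315). Stress genes fell in 15 of 19 with 1 higher (camera adjusted p = 8.52e-07, adjusted p = 0.268 with an estimated correlation). In all, 14311 of 22370 genes passed, and 13880 with the WT pairs summed. Against the TMM scaling, size factors of the RLE method moved the median of all genes by 0.105. Among 16224 genes tested in both comparisons, 2363 were higher and 2369 lower in both SmoM2 and embryo than in WT, where independence would give 1234 and 1375, and 1041 went opposite ways. The WT libraries are shared, so WT was also divided into 3 libraries for each comparison. The median number of shared genes was then 4087.5 and the covariance of the fold changes 1.18. With all WT libraries shared it was 0.963, where simulated groups without change, which share WT likewise, gave 0.031. The simulated value covers only what the spread of shared WT libraries gives. The gate of WT differs from those of SmoM2 and embryo, and neither step removes this. With the WT pairs summed and each comparison using 2 of the 4, the median was 3381.5 genes and the covariance 1.2.

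Within the SmoM2 epithelium, cells positive for the Krt8-YFP reporter were compared with negative cells of the same genotype, the question being what marks the cells that switch on a columnar keratin. K8YFP+ cells carried more of the sorted gene, Krt8 reading 21.8 ± 15.8 CPM against 1.4 ± 1.67 (n = 3 and 3, 4.29 ± 0.87, adjusted p = 0.0146). Its partner Krt18 rose to 19.6 ± 22.5 CPM (4.27 ± 1.19, adjusted p = 0.0403) and Krt7 to 19.4 ± 22.2 from 0.468 ± 0.434 (5.64 ± 1.16). Squamous differentiation rose far more in absolute level. Krt13 rose to 13500 ± 3100 from 5000 ± 953 CPM (1.85 ± 0.29) and Krt4 to 6090 ± 1630 from 737 ± 403 (3.45 ± 0.50). The cornified envelope genes Ppl (1.84 ± 0.19) and Evpl (1.64 ± 0.16) and the transcription factor Grhl1 (1.86 ± 0.16) rose, and 27 of 35 squamous differentiation genes rose with none lower (32 adjusted over the list alone). Tight junction genes Cgn (1.97 ± 0.28) and Tjp3 (1.54 ± 0.22) and the epithelial factor Elf3 (1.23 ± 0.24) were among 9 of 16 simple epithelial genes that rose (12 adjusted over the list alone). Basal genes fell in 14 of 17 (15 adjusted over the list alone), with log2 folds of -1.17 ± 0.23 for Krt5, -1.25 ± 0.32 for Krt14 and -1.19 ± 0.23 for their regulator Trp63. The hemidesmosome integrins Itga6 (-1.41 ± 0.15) and Itgb4 (-1.42 ± 0.19) and the Notch ligand Jag2 (-1.40 ± 0.18) fell with them. Cell-cycle genes fell in 16 of 33 (28 adjusted over the list alone). With a replicate block 35 of 35 squamous differentiation and 12 of 16 simple epithelial genes rose. With it 15 of 17 basal genes fell and 1 rose, and 23 of 33 cell-cycle genes fell. Without a replicate block no gastric (2 tested), secretory (2) or endoderm factor (5) gene passed in edgeR, where 1 secretory gene did when adjusted over the list alone, and of 7 intestinal genes 1, the glucose transporter Slc5a1 (2.20 ± 0.30), rose. With the block 1 endoderm factor gene and 2 intestinal genes rose and 1 intestinal gene fell.

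Camera with a preset correlation gave adjusted p = 5.07e-15 for squamous differentiation, 7.05e-11 for cell cycle, 1.2e-06 for squamous basal and 0.000113 for simple epithelial genes. Hedgehog genes (0.00274) were lower in K8YFP+ cells in 4 of 14, and in 7 with the replicate block. None passed with the other setting, each having adjusted p = 0.516 with an estimated correlation. Stress genes also passed upward (0.00741, adjusted p = 0.726 with an estimated correlation, 2 of 19 higher and 9 with the replicate block). Gli1 read 62.1 ± 37.3 CPM in K8YFP+ and 158 ± 42.9 in K8YFP- (-0.96 ± 0.42, adjusted p = 0.136) and Ptch1 509 ± 336 and 1300 ± 452 (adjusted p = 0.174). Residuals of equal replicate numbers were correlated across the 2 gates, so the replicate number was also used as a block. In it Gli1 (-1.07, adjusted p = 0.00519) and Ptch1 (-1.18, adjusted p = 0.00944) fell, and 4785 genes passed against 3110 of 15598 without the block (2045 higher, 1065 lower). Both were also called with no filter on low counts (0.0119 and 0.0157) and in the fit of all 14 groups (0.00122 and 0.00239), and with block and thinning Ptch1 was called (0.0109) and Gli1 was not. Sox9 (110 ± 5.3 and 138 ± 22.8 CPM, 0.07 ± 0.16), Sox2 (0.11 ± 0.24), Smo (-0.12 ± 0.14) and Epcam (0.02 ± 0.27) did not pass, and Hhip was too low to be tested. The largest rises were in the cytochrome P450 gene Cyp2a5 (5.03 ± 0.91), Igf1 (5.08 ± 1.10), Rnf224 (5.00 ± 0.68), the beta-defensin gene Defb6 (4.93 ± 0.99) and Krt7. The largest falls were in Parpbp (-2.52 ± 0.54), the matrix gene Tnc (-2.01 ± 0.33), Fhl3 (-1.94 ± 0.54), Ankrd6 (-1.90 ± 0.40) and the metalloproteinase gene Adam8 (-1.85 ± 0.34). Fibroblast markers rose together with the differentiation genes in 8 of 12 (11 adjusted over the list alone and 11 with the replicate block). Their camera adjusted p was 0.000506, and adjusted p = 0.603 with an estimated correlation. Col1a1, again named after its values were seen, stood at 48.3 ± 36.2 CPM against 5.25 ± 3.46. Immune markers rose in 3 of 6 and endothelial ones in 1 of 4 with none lower, no muscle marker of 4 passed (3 higher adjusted over the list alone), and 1 of 3 neural markers fell. None of these lists passed (0.184, 0.12, 0.617 and 0.639). K8YFP+ replicate 2 was the shallowest library (1.61 M counts), with 13.8% of counts in ribosomal-RNA-like genes against 4.22% to 9.32% in the other 5. Mitochondrial genes held 3.09% to 7.38% of counts in K8YFP+ and 2.2% to 2.28% in K8YFP- libraries. With the replicate block and all libraries, Krt18 (adjusted p = 0.000497), Krt8 (0.000422), Krt7 (0.00114), Krt14 (0.00226) and Elf3 (0.000608) were called. So were Ankrd6 (0.00218), Igf1 (0.0038), Adam8 (0.00455), Defb6 (0.0104), Parpbp (0.0113) and Fhl3 (0.017). Without the block several calls ended when 1 library was left out, which was not tried with the block. Krt18 ended without K8YFP+ 1 or 2 or any K8YFP- library (adjusted p 0.0553 to 0.127). Krt14 (0.0533 to 0.072) and Fhl3 (0.0501 to 0.123) ended without any K8YFP+ library or K8YFP- 2 or 3. Parpbp ended without K8YFP+ 1 (0.06), Defb6 without K8YFP+ 3 (0.0549) and Igf1 without K8YFP- 2 (0.0571). Without K8YFP- 3 the count of genes was 1016, and Krt7 (0.064), Krt8 (0.0633), Elf3 (0.0619), Ankrd6 (0.0628), Parpbp (0.056), Defb6 (0.0583) and Igf1 (0.0619) were not called. With all libraries thinned to the smallest, 1171 genes passed and Ankrd6 (0.0971), Elf3 (0.0934) and Adam8 (0.0562) did not.

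**Figure D2:**
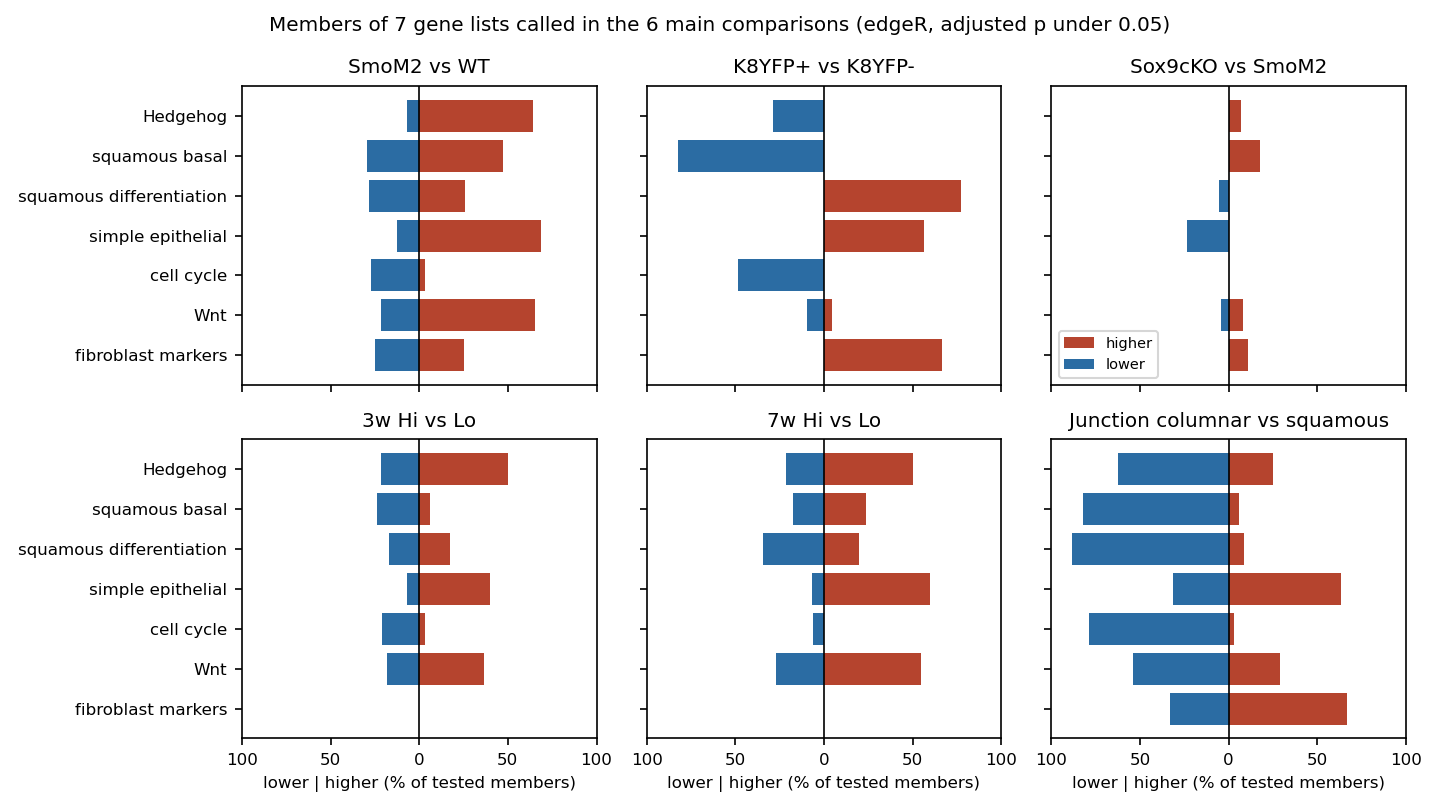
Percent of the tested members of 7 gene lists that were higher (right, red) or lower (left, blue) in each of the 6 main comparisons, from 0 at the centre line. In K8YFP+ against K8YFP- cells, fitted without a replicate block, 27 of 35 squamous differentiation genes were higher, and at the junction 31 of 35 were lower in columnar cells.

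The junction libraries gave the normal columnar and squamous programmes against which K8YFP+ cells could be held (n = 4 and 3). Columnar cells held Krt8 at 770 ± 341 against 2.9 ± 1.56 CPM (7.74 ± 0.44) and Krt18 at 1090 ± 106 against 20.3 ± 2.31 (5.43 ± 0.14), while Krt7 was lower in them than in the squamous cells (123 ± 39.6 against 187 ± 10.5 CPM, -0.92 ± 0.20). Gastric genes were highest in columnar cells, with the pepsinogen gene Pgc at 10800 ± 2890 CPM, Gkn1 at 1510 ± 248, Ctse at 1210 ± 150 and Anxa10 at 753 ± 38 (10.33 ± 0.21). Bpifb1, the chitinase gene Chia1, Dpcr1 and Gkn2 had no squamous count and were at least 23100-fold, 14600-fold, 10700-fold and 11000-fold higher. The endoderm factors Hnf4a (8.81 ± 0.26), Gata6 (7.55 ± 0.23) and Gata4 (5.46 ± 0.16), the apical genes Vil1 (9.03 ± 0.33), Prom1 (9.67 ± 0.24) and Cftr (5.79 ± 0.25), and the mucosal genes Muc1 (8.61 ± 0.19), Pigr (9.84 ± 0.41) and Cxcl17 (7.97 ± 0.24) rose too. Sox9 stood at 381 ± 107 CPM in columnar and 146 ± 22.5 in squamous cells (1.07 ± 0.20) and Epcam at 547 ± 46.5 and 207 ± 21.4. The basal genes Krt5 (-8.39 ± 0.38), Krt14 (-8.75 ± 0.21), Trp63 (-7.86 ± 0.31), Col17a1 (-7.46 ± 0.26) and Cdh3 (-4.44 ± 0.17) were lower in columnar cells. So were Krt13 (-7.82 ± 0.35), Krt4 (-3.94 ± 0.52), Krt16 (-11.03 ± 0.21), Krtdap (-10.36 ± 0.20), Tgm1 (-12.08 ± 0.22), Serpinb2 (-12.47 ± 0.32), Smo (-1.27 ± 0.16) and Slc5a1 (-4.23 ± 0.18). Sprr2d and Calcb had no columnar count and were at least 904-fold and 820-fold lower, and Gpnmb (272 ± 74.2 CPM in squamous cells) and Pi15 (268 ± 32.3) had 1 columnar count each. Gli1 was lower in columnar cells (0.207 ± 0.154 against 16.9 ± 2.98 CPM, -6.41 ± 0.34), Ptch1 (-0.24 ± 0.12, adjusted p = 0.0879) and Sox2 (0.01 ± 0.13) did not pass, and Hhip was not tested. All 19 gastric, 15 of 17 endoderm factor, 17 of 21 intestinal, 13 of 14 secretory and 12 of 19 simple epithelial genes rose (6 of the last fell, and the list did not pass, camera adjusted p = 0.0799), while 31 of 35 squamous differentiation and 14 of 17 squamous basal genes fell. The counts were equal when adjusted over the list alone. Camera held with both correlations for gastric (adjusted p = 2.02e-10, and adjusted p = 0.0346 with an estimated correlation) and endoderm factor genes (3.67e-05 and 0.0485). It was lost with the estimated one for squamous differentiation (2.02e-10, adjusted p = 0.105 with an estimated correlation), squamous basal (8.14e-05, then 0.293), secretory (3.86e-05, then 0.105) and intestinal genes (0.000782, then 0.105). Enteroendocrine (0.000547) and interferon genes (0.00942) passed upward and cell-cycle (8.14e-05) and stress genes (0.00194) downward with the preset correlation alone. Immune markers rose in 5 of 8 and fell in 2 without passing as a list (adjusted p = 0.492), Ptprc, named after its values were seen, reading 87.2 ± 27.6 against 0.0987 ± 0.0857 CPM. The female-specific Xist averaged 3170 ± 1170 CPM in columnar and 3.07 ± 0.196 in squamous libraries, and 12783 of 17185 genes passed. The leading number in the raw library names also differs between all columnar and all squamous libraries. In the fit of all 14 groups Krt7 was not called (adjusted p = 0.0896).

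Set against normal columnar tissues, K8YFP+ cells kept a squamous profile (n = 3 against 4 junction columnar, 2 stomach and 2 gut libraries). Krt13 was higher by 11.25 ± 0.36 than in junction columnar cells, 10.48 ± 0.49 than in stomach and 10.30 ± 0.49 than in gut, and Krt5 by 6.22 ± 0.36, 9.56 ± 0.61 and 6.83 ± 0.52. Trp63 was higher by 6.97 ± 0.29 than in junction columnar cells, at least 1080-fold higher than in stomach, and read 300 ± 109 against 0.494 ± 0.309 CPM in gut. Krt8 was lower in K8YFP+ cells by each comparison, at -4.87 ± 0.58, -4.13 ± 0.60 and -6.65 ± 0.64, the references holding 770 ± 341, 392 ± 20.9 and 1740 ± 1940 CPM. Krt7 was lower than in junction columnar cells (-2.51 ± 0.58) and gut (-4.07 ± 0.64). It did not pass against stomach (-1.14 ± 0.64, adjusted p = 0.137) and did so without K8YFP+ 2 (adjusted p = 0.00328) or stomach 2 (0.0276). Gli1 was higher than in junction columnar cells by 8.46 ± 0.42, and stood at 0.0656 ± 0.0927 CPM in stomach and 0.275 ± 0.389 in gut. Sox9 was lower than in junction columnar cells (-1.38 ± 0.32), higher than in gut (1.39 ± 0.40) and did not pass against stomach (0.02 ± 0.37, adjusted p = 0.997), the gut call being lost without gut 1 (adjusted p = 0.0938). The squamous genes Tgm3 (3520 ± 475 against 0.0904 ± 0.181 CPM) and Serpinb3a (at least 5480-fold) led the genes higher than in junction columnar cells. Krtdap (at least 8560-fold) and Calm4 (at least 3530-fold) led those against stomach, and Sprr3 (at least 4670-fold) and Cyp2f2 (at least 2220-fold) those against gut. The tissues led with Bpifb1 (at least 14100-fold), Chia1 (at least 8880-fold), Ctse (0.137 ± 0.131 CPM in K8YFP+) and Agr2 (-9.35 ± 0.42) in junction columnar cells. Leading genes were Vsig1 (at least 5340-fold), Pik3c2g (at least 700-fold) and Gata6 (-8.06 ± 0.64) in stomach, and Zg16 (at least 5790-fold), the Paneth cell defensin Defa24 (at least 1890-fold) and the mucin Muc2 (-13.87 ± 0.50) in gut. Slc5a1 was higher in K8YFP+ than in junction columnar cells (6.80 ± 0.40), and Sox21 read 76.8 ± 18 against 0.413 ± 0.584 CPM in gut. All 19 gastric genes were lower than in junction columnar cells and 18 of 19 than in stomach, 29 of 32 intestinal genes were lower than in gut, and 34, 33 and 33 of 36 squamous differentiation genes were higher than in the 3 tissues. These calls passed camera with both correlations, the highest adjusted p being 0.0133 with an estimated correlation. Fibroblast markers were higher in K8YFP+ in 12 (with 1 lower), 12 and 8 of 13 than in junction columnar cells, stomach and gut (camera adjusted p = 0.00325, 0.000427 and 0.0173, and adjusted p = 0.313, 0.249 and 0.412 with an estimated correlation). Against stomach 6 of 11 immune markers were higher and 1 lower (0.0405, adjusted p = 0.13 with an estimated correlation). Against junction columnar cells, stomach and gut, muscle markers were higher in 8, 7 and 6 of 10 (1 lower against gut). That list did not pass (camera adjusted p = 0.0573, 0.104 and 0.34). Stress genes were higher in 16, 16 and 15 of 19, with 1 lower against stomach. Their camera adjusted p was 1.24e-06, 1.57e-07 and 3.69e-06, and 0.148, 0.0933 and 0.127 with an estimated correlation. Defa24 was not called by DESeq2 (adjusted p = 0.138). The totals were 13593, 11270 and 11030 of 22370 genes. Overlap was counted among 14594 genes tested in both K8YFP+ against K8YFP- and columnar against squamous junction. Of these 524 were higher in both, below the 619.4 that independence would give. Fisher's exact test was one-sided for an excess, so it does not measure this shortfall. A further 638 were lower in both (410.4 by independence, one-sided Fisher's exact p = 3.03e-49), while 1144 went opposite ways. At an absolute log2 fold of at least 1, 232 were higher in both (213.2 by independence, one-sided Fisher's exact p = 0.0759). At that threshold 184 were lower in both (98.63, one-sided Fisher's exact p = 1.37e-20). The fold changes had r = -0.0369 across genes, which are not independent replicates.

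**Figure D3:**
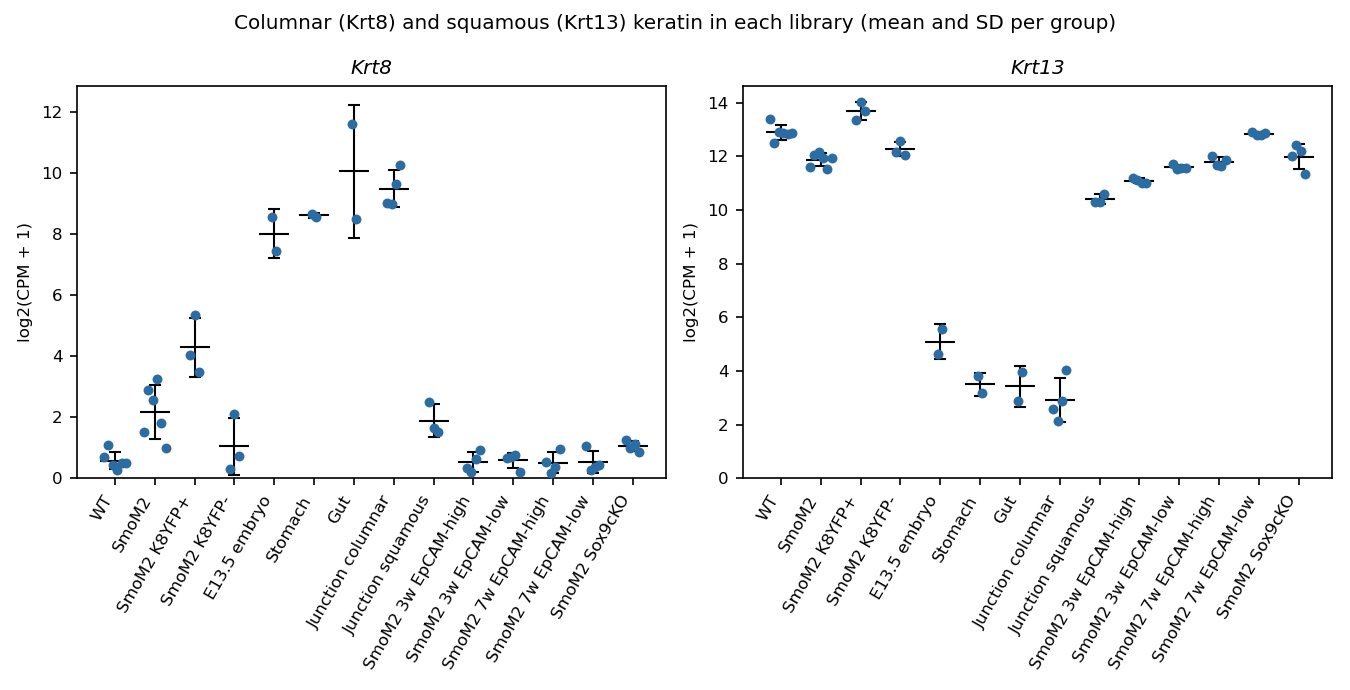
Krt8 and Krt13 in each of the 51 libraries as log2(CPM + 1), with the mean and SD of each group. K8YFP+ cells average 21.8 CPM of Krt8, between K8YFP- cells (1.4) and junction columnar cells (770), and hold Krt13 at 13500 CPM, where junction columnar cells hold 7.58.

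Deletion of Sox9 in SmoM2 cells asked which changes need this factor. Sox9 reads persisted. The Sox9cKO libraries 1 to 4 held 51.7, 45.7, 127 and 45.8 CPM and the SmoM2 libraries 1 to 6 held 194, 82.6, 72.7, 116, 85.3 and 94.6 CPM. The difference was -0.62 ± 0.36 (n = 4 and 6, adjusted p = 0.361). The exact permutation test, two-sided, gave p = 0.0857, adjusted 0.133 over 56 gate tests. The library labelled Sox9cKO replicate 3 lay within the SmoM2 range, but above every SmoM2 library other than SmoM2 1. SmoM2 1 also differs from all other libraries of this comparison in high Xist and in the leading number of its raw name. Simple epithelial keratins fell. Krt20 fell to 3.22 ± 0.689 from 38.6 ± 11.6 CPM (-3.52 ± 0.32, adjusted p = 0.000204), Krt7 to 0.309 ± 0.26 from 5.48 ± 3.56 (-3.96 ± 0.75), and Krt18 to 1.08 ± 0.377 from 3.87 ± 1.6 (-1.77 ± 0.40, adjusted p = 0.0354), while Krt8 read 1.11 ± 0.255 against 4.21 ± 2.94 (-1.85 ± 0.55, adjusted p = 0.0921). The tight junction gene Cldn7 fell by 1.75 ± 0.38 and the endoderm factor Foxa1 by 0.61 ± 0.13 on the log2 scale. Mal, a membrane traffic gene (-3.44 ± 0.53), the cornified envelope gene Sprr2d, which has close copies (-2.82 ± 0.66), and the Wnt effector Lef1 (-2.33 ± 0.49) fell. The largest falls besides Krt7 were in the muscarinic receptor Chrm3 (-4.30 ± 0.44), the kinase gene Grk3 (-4.83 ± 1.12, with 22.2 CPM in SmoM2 1 and 1.55 to 3.23 in the other 5), the surface protein gene Psca (-4.31 ± 0.78) and S100a9 (-4.16 ± 0.70), an alarmin of stressed epithelium and of myeloid cells. Of the Hedgehog genes, Gli1 (0.41 ± 0.14, adjusted p = 0.122), Ptch1 (0.33 ± 0.18, adjusted p = 0.314) and Smo (0.11 ± 0.13) did not pass, and the co-receptor Gas1 rose (1.46 ± 0.22). A few adhesion and signalling genes rose, Lamb3 by 0.74 ± 0.13, Itgb4 by 0.49 ± 0.09, Jag2 by 0.52 ± 0.09, Wnt7b by 0.72 ± 0.16 and Wnt10a by 0.73 ± 0.17. They are called members of lists in which most genes did not pass (3 of 17 squamous basal and 2 of 24 Wnt genes rose). Krt14 (0.74 ± 0.20, adjusted p = 0.0681), Krt5 (0.67 ± 0.17, adjusted p = 0.0598), Krt4 (-0.92 ± 0.55), Krt13 (0.21 ± 0.20), Trp63 (0.28 ± 0.15), Sox2 (0.11 ± 0.29) and Epcam (-0.13 ± 0.14) did not pass, and Hhip was not tested. The largest rises were in Arhgap8 (5.46 ± 0.50), the pseudogene BC002163 (3.66 ± 0.31), Glyat (2.39 ± 0.30), the potassium channel gene Kcns3 (2.21 ± 0.32) and the collagen Col14a1 (1.73 ± 0.34).

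By list, 4 of 17 simple epithelial genes fell (5 adjusted over the list alone), 2 of 35 squamous differentiation genes fell (4) and 1 of 5 endoderm factor genes fell (1). By contrast 1 of 14 Hedgehog genes rose (8 adjusted over the list alone), 3 of 17 squamous basal genes rose (9) and 2 of 24 Wnt genes rose with 1 lower (6 and 4). Camera gave adjusted p = 3.06e-05 for squamous basal, 6.64e-05 for Hedgehog, 0.000745 for simple epithelial and 0.00865 for squamous differentiation genes, and these became adjusted p = 0.163 with an estimated correlation for the first pair, then 0.224 and 0.535. The preset correlation also passed cell-cycle, stress and fibroblast genes (7.35e-05 each) and interferon genes (0.0171) upward. It passed intestinal (0.00536), fetal (0.00657), immune (0.0171, 2 of 8 lower) and gastric genes (0.0183) downward, and no list passed with an estimated correlation. Wnt genes had a median of 0.00956 and a mean of -0.245. Fibroblast markers moved with the basal genes, with Lum (2.01 ± 0.46, named after its values were seen) called among 9 and 7 higher when adjusted over the list alone. In all, 454 of 17047 genes passed, 201 higher and 253 lower. A block by replicate number, which the residuals gave no ground for, left 125 genes, and Krt20 and Krt7 passed in it. The count was 207 without the library labelled Sox9cKO replicate 3, 219 without Sox9cKO 1 and 2153 without Sox9cKO 2. It was 230, 263 and 250 without SmoM2 2, 3 or 5. Other calls ended when 1 library was left out. Krt18 ended without SmoM2 1, 2, 4 or 5 or Sox9cKO 1, 3 or 4 (adjusted p 0.0533 to 0.105), and Cldn7 without SmoM2 2 or Sox9cKO 1, 3 or 4 (0.0674 to 0.0875). Foxa1 ended without SmoM2 2, 4 or 5 or Sox9cKO 1, 3 or 4 (0.0556 to 0.102), and Sprr2d without any SmoM2 library or Sox9cKO 1, 3 or 4 (0.0547 to 0.111). Lef1 ended without SmoM2 2 or 3 or Sox9cKO 1 or 3 (0.0515 to 0.0773), and Grk3 without those or Sox9cKO 4 (0.0577 to 0.112). Wnt7b ended without SmoM2 2, 3 or 5 or Sox9cKO 1, 3 or 4 (0.0579 to 0.087), and Wnt10a without SmoM2 2 to 6 or Sox9cKO 1 or 3 (0.07 to 0.124). Col14a1 ended without SmoM2 5 (0.0507) or Sox9cKO 4 (0.0563), Itgb4 without Sox9cKO 3 (0.0504) and Krt7 without Sox9cKO 1 (0.0576). The block by replicate number ended Jag2 (0.0685), Itgb4 (0.118), Lamb3 (0.058), Foxa1 (0.124), Grk3 and Wnt10a (0.053 each), Lef1 (0.0909), Sprr2d (0.0746) and Wnt7b (0.0592), and the fit of all 14 groups ended Lamb3 (0.0923), Krt18 (0.064) and Foxa1 (0.0601). Calls were gained for Krt14 (0.0223 and 0.0192) and Krt5 (0.0208 and 0.0228) without SmoM2 1 or Sox9cKO 2, for Krt8 (0.036) without SmoM2 6 and for Krt4 (0.0394) without Sox9cKO 2. Krt8, Krt14 and Krt5 were also called by DESeq2 (0.0145, 0.0128 and 0.00729) and with no filter on low counts (0.0407, 0.0217 and 0.0214). Of the genes higher in SmoM2 than in WT, 137 fell in Sox9cKO (59.19 by independence) and of those lower in SmoM2, 49 rose (44.54), among 16076 genes. With separate SmoM2 libraries for the 2 comparisons the medians were 28 (11.51 by independence) and 4 (3.734).

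**Figure D4:**
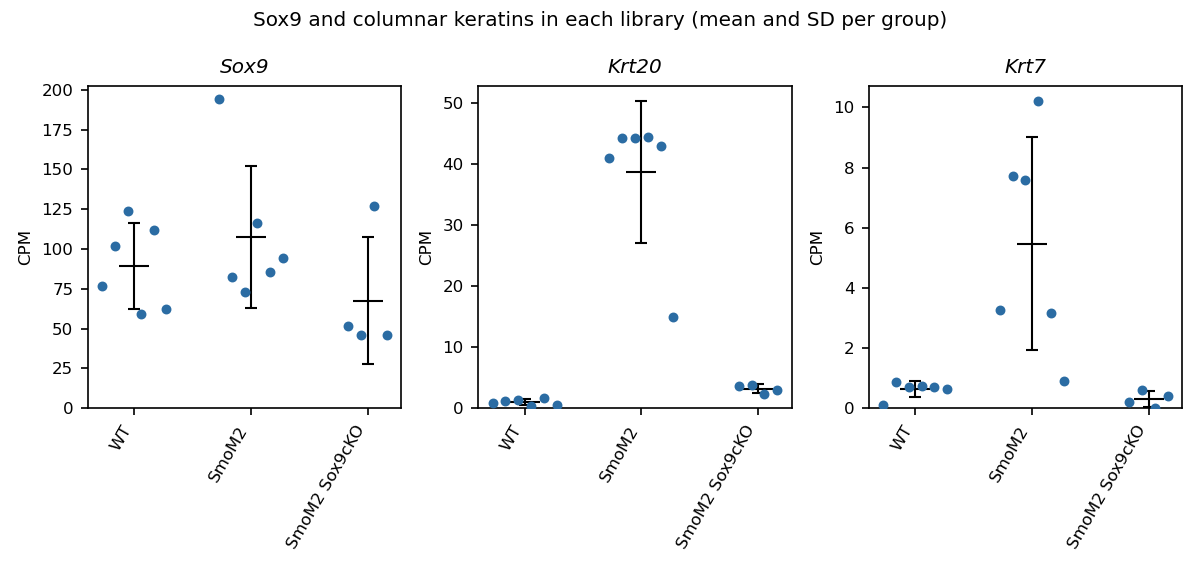
CPM of Sox9, Krt20 and Krt7 in each WT (n = 6), SmoM2 (n = 6) and Sox9cKO (n = 4) library, with the mean and SD of each group on axes from 0. Krt20 averages 38.6 CPM in SmoM2 and 3.22 in Sox9cKO, whereas the Sox9 values of the groups overlap.

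The time series compared EpCAM-high with EpCAM-low SmoM2 cells at 3w and 7w. Whether the 2 gates hold stages of 1 state was not tested. At 3w Gli1 read 106 ± 10.7 CPM in EpCAM-high and 16.6 ± 0.853 in EpCAM-low cells (n = 4 and 4, 2.62 ± 0.14, adjusted p = 3.55e-12), Ptch1 843 ± 57.9 and 112 ± 9.96 (2.86 ± 0.12) and Gli2 91.2 ± 6.18 and 16.3 ± 1.82 (2.43 ± 0.16). Smo rose by 1.03 ± 0.10, and the sorted gene Epcam by 0.73 ± 0.10. Krt20 (2.15 ± 0.25) and the tight junction gene Ocln (1.63 ± 0.20) rose. Krt10 rose (2.58 ± 0.27) while Krt4 (-2.16 ± 0.26), Krt13 (-0.56 ± 0.13) and the protease inhibitor Cstb (-0.60 ± 0.08) fell. Basal Krt14 (-0.54 ± 0.10), Krt15 (-0.40 ± 0.09) and Jag2 (-0.43 ± 0.10) and the cell-cycle genes Ccnd1 (-0.91 ± 0.14), Mcm5 (-0.95 ± 0.19) and Mcm3 (-0.77 ± 0.18) fell. Krt5 (-0.07 ± 0.14), Trp63 (0.19 ± 0.08, adjusted p = 0.111), Sox2 (0.03 ± 0.16), Krt18 (-0.86 ± 0.35, adjusted p = 0.101) and Sox9 (0.50 ± 0.20, adjusted p = 0.101) did not pass, and Krt8, Krt7 and Hhip were too low to be tested. The largest rises were in Plekhg1 (4.48 ± 0.51), Srgap1 (4.11 ± 0.25), the lipoxygenase gene Alox12e (3.79 ± 0.38), Calm4 (3.66 ± 0.39) and the fucosyltransferase gene Fut9 (3.65 ± 0.30). The largest falls were in the amino acid transporter gene Slc7a8 (-3.43 ± 0.35), Wnt16 (-3.34 ± 0.56), the guidance gene Sema3d (-2.92 ± 0.20), Lypd6 (-2.79 ± 0.26) and Dynap (-2.56 ± 0.16). Hedgehog genes rose in 7 of 14 and fell in 3 (camera adjusted p = 0.0517), and simple epithelial genes rose in 6 of 15 and fell in 1 (0.00113, adjusted p = 0.0926 with an estimated correlation). With the replicate block the simple epithelial list passed with both (0.000885, and adjusted p = 0.0199 with an estimated correlation). Squamous differentiation genes rose in 6 and fell in 6 of 35, squamous basal genes rose in 1 and fell in 4 of 17, and cell-cycle genes rose in 1 and fell in 7 of 33. Adjusted over the list alone these were 7 and 6, 7 and 2, 9 and 6, 1 and 5, and 1 and 8. Stress genes fell in 3 of 19 (camera adjusted p = 0.0126, adjusted p = 0.585 with an estimated correlation). Cell-cycle genes had a median of 0.0985 and a mean of -0.0913. In all, 2625 of 17263 genes passed, 1272 higher and 1353 lower, and with the replicate number as a block, for which the residuals of equal numbers gave ground, 2389. In a fit of all 14 groups Krt13 (adjusted p = 0.17), Krt14 (0.353), Krt15 (0.542), Jag2 (0.0617) and Mcm3 (0.115) were not called. Trp63 was called without EpCAM-high 2 (0.0296), Sox9 with no filter on low counts (0.00956), and with only these groups fitted Sox9 (0.000908), Trp63 (0.0464) and Krt18 (0.0309) were called.

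At 7w the gap between the gates was wider for Hedgehog targets. Gli1 stood at 167 ± 16.8 CPM in EpCAM-high and 8.35 ± 2.49 in EpCAM-low cells (n = 4 and 4, 4.26 ± 0.15), Ptch1 at 1770 ± 137 and 89.4 ± 17.8 (4.27 ± 0.13) and Gli2 at 166 ± 19 and 9.72 ± 2.52 (4.05 ± 0.17). Smo rose by 1.23 ± 0.10 and Epcam by 1.08 ± 0.10, together with Krt20 (2.76 ± 0.27), Cldn8 (1.66 ± 0.17), Krt10 (3.07 ± 0.23), Sox9 (1.12 ± 0.21, 86.2 ± 16.8 against 38.5 ± 2.59 CPM), Sox2 (0.72 ± 0.16) and Trp63 (0.47 ± 0.08). Krt4 fell to 515 ± 275 from 5240 ± 644 CPM (-3.40 ± 0.27), and Krt13 (-1.09 ± 0.13), Cstb (-1.08 ± 0.08), Krt14 (-0.80 ± 0.10), Krt15 (-0.80 ± 0.09), Pax9 (-0.55 ± 0.09), Ccnd1 (-0.65 ± 0.13), Krt18 (-1.34 ± 0.43, adjusted p = 0.0192) and Rrm2 (-0.59 ± 0.21, adjusted p = 0.0342) fell, while Krt5 did not pass (-0.01 ± 0.14). The stem cell factor receptor gene Kit, at 8.31 ± 3.16 CPM, had no count in EpCAM-low cells and was at least 68.7-fold higher. S100g (14.6 ± 3.59 against 0.131 ± 0.0894 CPM), Wdr72 (11.5 ± 1.26 against 0.0494 ± 0.0988), Upk1b (7.56 ± 2.62 against 0.0877 ± 0.103) and B4galt5 (5.92 ± 0.43) were the other leading genes in EpCAM-high cells. Leading in EpCAM-low cells were Slc7a8 (-4.56 ± 0.34), Lypd6 (-4.28 ± 0.27), Dynap (-4.05 ± 0.17), the melanosomal and lysosomal gene Gpnmb (-4.04 ± 0.23) and the growth factor protease gene Pappa (-4.03 ± 0.42). Hedgehog genes rose in 7 of 14 and fell in 3 (camera adjusted p = 0.00459, adjusted p = 0.2 with an estimated correlation), and simple epithelial genes rose in 9 of 15 and fell in 1 (0.00158, adjusted p = 0.106 with an estimated correlation). Squamous differentiation genes rose in 7 and fell in 12 of 35, squamous basal genes rose in 4 and fell in 3 of 17, and 2 of 33 cell-cycle genes fell. Adjusted over the list alone these were 7 and 4, 9 and 1, 7 and 12, 4 and 3, and 1 lower. The test for squamous differentiation pointed down while median (0.138) and mean (0.124) were above 0. Wnt genes rose in 12 of 22 and fell in 6 (camera adjusted p = 0.0187, adjusted p = 0.269 with an estimated correlation). In all, 5584 genes passed, 2682 higher and 2902 lower (5452 with the replicate number as a block). Krt18 was lost without EpCAM-high 3 (adjusted p = 0.0696) or 4 (0.0669) or EpCAM-low 1 (0.103), and Rrm2 without EpCAM-high 1, 2 or 3 or EpCAM-low 1 or 2 (0.0502 to 0.153). In the fit of all 14 groups Krt14 (adjusted p = 0.0537), Krt15 (0.0501), Pax9 (0.0922), Trp63 (0.0825), Krt18 (0.29) and Rrm2 (0.113) were not called.

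**Figure D5:**
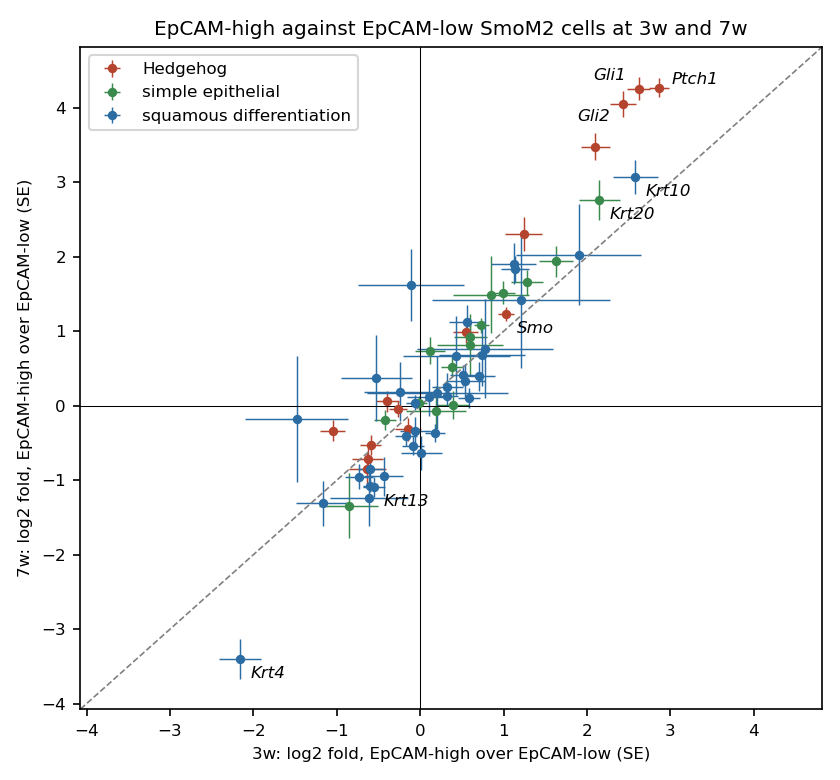
Log2 fold of EpCAM-high over EpCAM-low SmoM2 cells at 3w (x axis) and 7w (y axis) for members of the Hedgehog, simple epithelial and squamous differentiation lists, with SE on both axes and the line of equal folds. Gli1 (2.62 and 4.26), Ptch1 (2.86 and 4.27) and Gli2 (2.43 and 4.05) lie above the line.

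The difference between the gates was itself tested against time. It was larger at 7w for Gli1 (by 1.64 ± 0.20, adjusted p = 5.64e-05), Ptch1 (1.41 ± 0.16), B4galt5 (3.87 ± 0.66) and the cadherin gene Cdh11 (3.77 ± 0.76), and lower for Pappa (-2.68 ± 0.55) and the cystine transporter gene Slc7a11 (-2.15 ± 0.29). Krt13 (-0.53 ± 0.19, adjusted p = 0.16), Krt5 (0.07 ± 0.20) and Sox9 (0.62 ± 0.29, adjusted p = 0.369) did not pass. Krt13 was called with no filter on low counts (0.0448), and with only these groups fitted Krt13 (0.00271) and Sox9 (0.0499) were called. Of 14 Hedgehog genes 4 had a larger difference at 7w (6 adjusted over the list alone), and camera passed with both correlations (adjusted p = 2.45e-06, and adjusted p = 0.0238 with an estimated correlation). So did hair follicle genes, 2 of 10 higher and 5 adjusted over the list alone (0.00413, and adjusted p = 0.0238 with an estimated correlation). Wnt genes were higher in 2 of 22, and in 8 adjusted over the list alone (0.00086, adjusted p = 0.0955 with an estimated correlation). In all, 398 genes passed, 267 higher and 131 lower, and 42 in a fit of all 14 groups, where Ptch1 (adjusted p = 0.0679), B4galt5 (0.0836), Cdh11 (0.703) and Slc7a11 (0.152) were not called. Within EpCAM-high cells, Gli1 rose from 3w to 7w (0.60 ± 0.12), as did Ptch1 (1.02 ± 0.11), Krt13 (0.66 ± 0.13), Cldn8 (1.52 ± 0.17), the kallikrein gene Klk14 (3.61 ± 0.71) and Nrxn3 (3.13 ± 0.42). Sox9 (-0.64 ± 0.20), Il15ra (-5.19 ± 0.43) and Samd5 (-4.61 ± 0.51) fell and Krt5 did not pass (0.31 ± 0.14, adjusted p = 0.0797). Within EpCAM-low cells Gli1 (-1.04 ± 0.16), Sox9 (-1.26 ± 0.21), the tight junction gene Marveld3 (-1.23 ± 0.16), the caldesmon gene Cald1 (-4.59 ± 0.26) and Fgd3 (-5.01 ± 0.55) fell. Krt13 (1.19 ± 0.13), the amino acid transporter gene Slc6a19 (2.62 ± 0.50) and Smtnl2 (2.83 ± 0.42) rose, and Krt5 did not pass (0.25 ± 0.14). Krt8 and Krt7 were too low to be tested in all 3. Squamous differentiation genes rose in 21 of 35 and fell in 4 in EpCAM-high cells (camera adjusted p = 0.00106, adjusted p = 0.705 with an estimated correlation) and rose in 21 and fell in 5 in EpCAM-low cells (9.04e-05, adjusted p = 0.681 with an estimated correlation). The totals were 7150 and 6552 genes. All 8 libraries at 7w had low Xist (at most 13.2 CPM), whereas 3w replicates 1 to 3 of both gates had high Xist. Sex and time thus differ together. The leading number in the raw library names also differs between all 3w and all 7w libraries. With replicate 4 as the only 3w library, 3024 and 2284 genes passed. The Sox9 call in EpCAM-high cells was lost without 3w 4 (adjusted p = 0.0533) or 7w 2 (0.0628), and in the fit of all 14 groups (0.102). Krt5 was called in EpCAM-high cells without 7w 3 (0.0465) or with no filter (0.0112), and in both gates with only these groups fitted (0.00464 and 0.00582).

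EpCAM-low SmoM2 cells were compared with WT cells of the same gate, which asks what the genotype does without the EpCAM-high selection. Smo and transgene reads together were 0.0365 log2(CPM + 1) above WT at 3w (exact permutation test, two-sided, p = 0.805). At 7w they were 0.37 above WT (exact permutation test, two-sided, p = 0.019, adjusted 0.0616 over 56 gate tests). In SmoM2 against WT this difference was 1.46. What share of the EpCAM-low cells expressed the transgene was not tested. Gli1 was 16.6 ± 0.853 CPM at 3w and 8.35 ± 2.49 at 7w against 0.703 ± 0.277 in WT (n = 4, 4 and 6, 4.46 ± 0.20 and 3.42 ± 0.22), and Ptch1 rose from 19 ± 1.87 to 112 ± 9.96 and 89.4 ± 17.8 CPM. Krt13 fell by 1.39 ± 0.13 at 3w and did not pass at 7w (-0.19 ± 0.12, adjusted p = 0.211), and Krt5 fell by 0.61 ± 0.13 at 3w and by 0.37 ± 0.13 at 7w (adjusted p = 0.026). Sox9 did not pass at 3w (-0.08 ± 0.19) and fell by 1.34 ± 0.20 at 7w. The claudin gene Cldn4 fell by 1.80 ± 0.17 and 2.30 ± 0.18, Notch3 fell at 3w (-1.82 ± 0.12) and Krt16 at 7w (-1.43 ± 0.15). Squamous differentiation genes fell in 32 of 35 at 3w with 1 higher (camera adjusted p = 2.07e-14, adjusted p = 0.143 with an estimated correlation) and in 19 of 35 at 7w (22 adjusted over the list alone, 1.09e-06, adjusted p = 0.463 with an estimated correlation). Hedgehog genes rose in 6 and 8 of 14 with 1 lower each time (0.00405 and 0.000112, adjusted p = 0.143 and 0.0969 with an estimated correlation). Simple epithelial genes, most of which rose in SmoM2 against WT, rose in 4 of 15 and fell in 8 at 3w (camera adjusted p = 0.394). At 7w they rose in 3 and fell in 8, and the list passed downward (0.0171, adjusted p = 0.201 with an estimated correlation). Cell-cycle genes rose in 6 of 33 with 2 lower at 3w (adjusted p = 0.0942) and in 25 of 33 at 7w (4.64e-07, adjusted p = 0.48 with an estimated correlation). The receptor phosphatase gene Ptprd (6.81 ± 0.33) and the pseudogene Rps2-ps13 (6.19 ± 0.10) led the rises at 3w. The ephrin receptor gene Epha7 (5.79 ± 0.26) and Rps2-ps13 (6.05 ± 0.10) led those at 7w. The serpin genes Serpinb3c (0.0404 ± 0.0807 against 10.1 ± 8.7 CPM) and Serpinb3b (0.0785 ± 0.0907 against 8.5 ± 8.59), near copies of each other, led the falls at 3w. The interferon-inducible Ifi209 (at least 84.4-fold) and the heat shock gene Cryab (-6.56 ± 1.15, with 72.1 CPM in WT 1 and at most 15 in the other 5) led those at 7w. Krt8 and Krt7 were not tested. In all, 8187 genes passed at 3w and 6966 at 7w, and 7523 and 6106 with the WT pairs summed. Rpl29, a ribosomal protein gene named after its values were seen, read 212 to 323 CPM in the 16 libraries of the time series and 6.3 to 45.4 in the other 35, WT among them, so that the set of libraries and the genotype differ together in this comparison. The Krt5 call at 7w was lost without WT 2, 4 or 6 or EpCAM-low 1, 3 or 4 (adjusted p 0.0539 to 0.0632), and in the fits of all 14 groups (0.302) and of these groups only (0.111). The p-values here measure the spread between samples that the labels do not tie to separate animals.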

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

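A library was noted when its CPM for a named gene lay far from the other libraries of its group (gap to the nearest library over the range, Dixon's test), in groups of 4 to 10 libraries. Of 411 such sets of values 41 were noted, where normally distributed values give about 1 in 20 by chance. A gene with counts in 1 library and none in the others is always noted, as Hhip in WT was. The number noted lies above 1 in 20, and genes of this kind make up part of it. It therefore does not decide whether unusual libraries are in excess. All tests on Sox9 below and all counts over other splits of the libraries were chosen after the result was seen.

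In WT, replicate 1 was apart for Hhip (0.244 CPM), Krt7 (0.122), Trp63 (463), Slc6a11 (0.122), Col1a1 (9.62) and Cryab (72.1), replicate 2 for Ptch1 (15.3) and Prox1 (0.124) and replicate 6 for Sox11 (0.107). In SmoM2, replicate 1 was apart for Krt5 (3130), Krt15 (622), Sox9 (194), Wif1 (131) and Grk3 (22.2), replicate 4 for Gli1 (288), Krt10 (981) and Krt6b (1420), and replicate 6 for Krt20 (15) and Col14a1 (10.1). In junction columnar cells, Gkn2 (1290) and Gpnmb (0.17) stood apart in replicate 2, Pi15 (0.154) in replicate 1 and Tgm3 (0.361) in replicate 4. At 3w these were Hhip (0.131, replicate 4) and Samd5 (6.03, replicate 2) in EpCAM-high cells, and Sox9 (110, replicate 4), Slc7a8 (15.9, replicate 2), Slc6a19 (1.45, replicate 4), Cldn4 (62, replicate 3) and Serpinb3c (0.161, replicate 4) in EpCAM-low cells. At 7w they were Krt10 (253), Krt4 (926) and Fgd3 (0.152) in replicate 1 and Slc7a11 (6.72) in replicate 4 of EpCAM-high cells. In EpCAM-low cells at 7w they were Gli2 (5.97) and Krt20 (1.84) in replicate 3, Epcam (141) in replicate 1 and Wdr72 (0.198) in replicate 2. In Sox9cKO they were Arhgap8 (14.5, replicate 1), Sprr2d (12.2, replicate 2) and Sox9 (127, replicate 3).

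The library labelled Sox9cKO replicate 3 read 127 CPM of Sox9 against 45.7 to 51.7 in the other 3. This is within the SmoM2 range of 72.7 to 194, but above every SmoM2 library other than SmoM2 1. With the genes chosen without it, it lay at position 1.2 on the line from SmoM2 (0) to Sox9cKO (1), beyond every SmoM2 library (-0.0676 to 0.298), which argues against a wrong label. Admixed cells with an intact gene would have to make up a share of 1.33 at the mean Sox9 level of SmoM2, or 0.543 at the level of its highest library, to give 127 CPM. Shares of this size would place the library nearer SmoM2, which its position argues against. Transcripts of the deleted allele that are still counted remain a candidate explanation for the reads in all 4 libraries, since the other 3 average 47.8 CPM, and counts per gene cannot show whether the deleted part is present. The position of Sox9cKO replicate 2 was 0.249, inside the SmoM2 range.

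Effects that differed between 3w and 7w were noted through the interaction of gate and time, in which 398 genes passed. The named ones were B4galt5 (3.87), Cdh11 (3.77), Gli1 (1.64), Ptch1 (1.41), Pappa (-2.68) and Slc7a11 (-2.15) as the 7w minus the 3w log2 difference. Xist differs with time in these libraries, as does the leading number in their raw names. The part of sex or of that number in the interaction was not tested.

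Counts of passing genes were compared with counts from other splits of the same libraries into groups of equal size, fitted on those libraries alone. Chance was excluded for SmoM2 against WT (1 of 100 splits with as many, 8034 against a highest other of 1580), 7w against 3w in EpCAM-high (1 of 35, 8091 and 0) and EpCAM-low cells (1 of 35, 7516 and 0), the junction (1 of 35, 12783 and 0) and K8YFP+ against junction columnar cells (1 of 35, 10587 and 0). It was also excluded for EpCAM-low cells against WT at 3w (1 of 100, 6365 and 2345) and 7w (1 of 100, 4914 and 3061), where the highest other split set WT 3 to 6 against the rest and so points to a structure, WT 3 with 5 and WT 4 with 6 being near in their counts. With these pairs summed chance was excluded for SmoM2 against WT (1 of 100, 7398 and 51) and for EpCAM-low cells against WT at 3w (1 of 35, 5274 and 10) and 7w (1 of 35, 3445 and 0). For EpCAM-high against EpCAM-low cells, libraries moved freely gave as many in 1 of 35 splits at 3w (4474 and 1) and 7w (6071 and 0). Swaps within a replicate number, which the residuals at 3w call for, allow 8 splits, too few at 3w (4474, highest other 0) and at 7w (6071, highest other 0). For Sox9cKO against SmoM2, 2 of 100 splits gave as many (454), the other being 832 with SmoM2 4 in the place of Sox9cKO 2, which points to a structure in which Sox9cKO 2 is apart from its group. This other split gave more genes than the labelled groups did, so chance is not called excluded for Sox9cKO against SmoM2. For K8YFP+ against K8YFP- the 10 splits are too few (3110, highest other 0). For the interaction 6 of 100 splits gave as many (1099, highest other 6961), so that this set of splits does not exclude chance; moving libraries between time points within a gate carries the time effect into the interaction, which is a structure. With both gates of a number moved together 1 of 35 did (1099, highest other 0). This scheme takes equal numbers of the 2 gates as paired, which is undecided at 7w, and it too moves the time effect between groups. The 1099 genes come from a fit of these groups alone, where the main fit gave 398. Chance is therefore not called excluded for the interaction.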

How the results depend on the processing

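Thinning, fits of only the groups compared in the time series, choices by Xist and summing the WT pairs (3 with 5, 4 with 6) were added after the data were seen. No call of a named gene reversed, nor did a list that passed in both settings. Of 4734 gene results under alternatives, 4571 kept their side of the threshold, 130 lost a call and 33 gained one. Of 443 list results 349 kept their side of the threshold and 94 lost a call. These were 91 with the estimated correlation and 3 with the WT pairs summed (interferon at 7w, 0.0644, intestinal and fibroblast genes in the embryo, 0.0586 each). Lists that had not passed could not lose a call and are among the 349. Most lists that passed with the preset correlation did not pass with the estimated one. The summed pairs gave 7398 genes for SmoM2 against WT, 7523 and 6106 for EpCAM-low cells at 3w and 7w, 13880 for the embryo and an overlap of 3381.5. Other scaling (RLE) changed no named call. A minimum log2 fold of 1 left 2690 genes for SmoM2 against WT, 1832 for K8YFP+ against K8YFP-, 273 for Sox9cKO against SmoM2, 790 and 1827 between gates at 3w and 7w, 215 for the interaction, 1848 and 1706 for time in EpCAM-high and EpCAM-low cells, 2491 and 2081 for EpCAM-low cells against WT at 3w and 7w, and 8106 for the junction, and overlaps of 416, 1626 and 121. This follows from the stricter threshold. K8YFP+ against K8YFP- gave 6733 genes in the fit of all 14 groups, 4785 with the replicate block, 1171 thinned and 1560 thinned with the block. It gave 1016 to 2263 leaving out 1 library. Of these calls 65.8% were higher in the main fit, 59.7% with the block and 49.5% in the fit of all 14 groups. Sox9cKO against SmoM2 gave 767 without the filter, 1273 by DESeq2, 1524 in the fit of all 14 groups and 125 with the block. It gave 207 to 2153 leaving out 1 library. Of its calls 44.3% were higher in the main fit, 28% with the block and 35% without Sox9cKO 2. At 3w the gates gave 1378 genes in the fit of all 14 groups and 4474 with only these groups. The interaction gave 42 and 1099 in those fits. With the low-Xist 3w library alone, time gave 3024 and 2284 genes, from fewer libraries. K8YFP+ against stomach and gut gave 7287 and 5904 with only those groups. The overlap of SmoM2 with Sox9cKO was 32.5 with separate SmoM2 libraries. Unless stated, the cause was not tested. Leaving out 1 library gave 7357 to 8559 for SmoM2 against WT, 1996 to 2251 and 4658 to 5144 between gates at 3w and 7w, 308 to 400 for the interaction, 6150 to 6858 and 5408 to 6050 for time, 7233 to 8567 and 5877 to 7503 for EpCAM-low against WT, 12185 to 12401 for the junction and 11848 to 14254 for the embryo. For K8YFP+ against junction columnar, stomach and gut cells it gave 11827 to 13226, 8262 to 10659 and 8673 to 10735. Where 1 library remained in a group, it was assumed to vary like the others. By group total depth was lowest in gut, and K8YFP+ 2 was the shallowest library. In K8YFP+ against K8YFP- 17 of 100 simulated 2-fold changes were recovered, where depth, spread and the number of libraries were not separated.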

Other observations

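The endoderm factor Foxa2, chosen after its values were seen, had no count in WT, K8YFP-, junction squamous and all 16 time-series libraries. It was counted in 6 of 6 SmoM2 libraries (0.421, 3.96, 2.67, 2.78, 0.774 and 0.734 CPM), in 2 of 3 K8YFP+ libraries (0.895 and 1.24) and with 3 counts over the Sox9cKO group (0.0839 CPM). Embryo (29.9 ± 10.3), stomach (58.8 ± 11.8) and junction columnar cells (29.9 ± 1.86) held far more. Shh had counts in 6 of 6 SmoM2 libraries (0.768 ± 0.677 CPM) and 2 counts over WT, beside 182 ± 19.5 CPM in the embryo. The epidermal keratin Krt1, also chosen afterwards, read 24.3 ± 10.7 CPM in SmoM2, 37.6 ± 21.4 in Sox9cKO, 1.49 ± 1.41 in WT and 1250 ± 324 in junction squamous cells, and at most 2.44 as a mean in the time series.

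The tests of depth and scaling were set down before their results were seen, and every other test below was chosen after the result was seen. In K8YFP+ cells the squamous differentiation list had a median log2 fold of 2.08. With all libraries thinned to the smallest it was 1.86, and the lower of its value with RLE scaling and its value relative to all genes was 2.06, so that depth and scaling are excluded as the whole cause. Differentiated squamous cells in the YFP+ gate and a squamous programme within Krt8-positive cells cannot be told apart from these totals. Krt8 in K8YFP+ reached 2.83% of its junction columnar level, and 2.66% as a share of the junction columnar excess over K8YFP-. Of 10 other simple epithelial genes, 3 lay within 2-fold of that 2.66% (range -17.3% to 90.8%). By itself this neither requires nor rules out a small columnar share. All 19 tested gastric genes were lower in K8YFP+ than in junction columnar cells, with a median log2 fold of -11.3. A 2.66% share of cells like the junction columnar ones would leave these genes far less reduced. The gastric genes thus argue against such cells as the source of Krt8 at that level. A smaller share, or columnar cells without gastric genes, was not tested.

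In the 16 time-series libraries 7 of 17035 genes lay more than 1 log2 unit beyond all 35 others, Rpl29 above and Gm8210, Gm15459, Gm26825, Eno1b, Gm28438 and Gm11868 below. Pseudogenes made up 57.1% of them against 4.31% of all genes. The pattern was noticed in genes of this kind, and Gm15459 and Gm26825 overlap in the genome, so this share does not decide whether reads were assigned differently between gene copies in 1 set of libraries. SmoM2 genotype and EpCAM gate are excluded, since the 6 SmoM2 libraries lay with the other libraries for 7 of 7 genes chosen without them. Assignment of reads stays open, as do age and the day of processing, which were not tested.

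Rps2-ps13 read 128 ± 41.6 CPM in SmoM2, 126 in Sox9cKO replicate 4 and 78.2 in junction squamous replicate 1, against 1.63 ± 0.347 in WT. Xist was high in WT 1, SmoM2 1, replicate 3 of both K8 groups, 3w replicates 1 to 3, embryo and junction columnar libraries, and junction columnar 1 and 2 also had the Y-linked Ddx3y at 35.5 and 30.3 CPM.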
